A study of Danio rerio with 12 samples.

How the data were processed

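RNA from pools of whole larvae was hybridised to 1-colour Agilent zebrafish arrays, 12 in all, with 4 deposited per group. Per the file headers, the authors extracted the spots with Agilent Feature Extraction 11.0.1.1, and the deposited values of the scanner files are processed signals in intensity units on a linear scale, subtracted for background and detrended within each array, with no scaling between arrays. The series table holds the same intensity values: the largest log2 difference from the scanner files was 0 on all 12 arrays, so it was not analysed a second time. Groups, replicate numbers, doses and days were taken per the labels, and the array to leave out per the design text. Flags for well above background and for spot quality come from the scanner files.

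Spots of the same probe were averaged after leaving out spots flagged as non-uniform or as population outliers, which gave 43603 probes. Probes were named through their RefSeq accession with the RefSeq gene table of assembly GRCz12tu, used for names only; the file headers give Zv8 as the build of the array design, and no positions are reported. This named 25069 probes of 12858 genes, while 18534 probes, 9257 of them with an Ensembl transcript identifier, stayed without a symbol. The processed signal was log2 transformed and scaled by subtracting the 75th percentile of each array over the probes that are not controls. A probe entered the fit if it was well above background on at least 3 of the 11 arrays, and the brightest probe stood for each gene.

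Group means were fitted to 11 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 2.69 prior degrees of freedom), without covariates. The 3 contrasts were T0901317 against DMSO, GW3965 against DMSO and T0901317 against GW3965. Adjusted p values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05 with no fold minimum. Intervals cover 95%. For 32 gene lists (lipid pathways, xenobiotic and stress responses, and markers of the cell types of the larva), camera was run with a preset correlation of 0.01 and with an estimated correlation, each adjusted over the lists of a contrast; lists needed at least 3 measured members. Camera compares the genes of a list with all other genes. Choices of samples, tests, lists, named genes and alternatives were made before the data were examined, except for the alternatives and tests that the closing section names as later ones.

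Genes named in the text were taken from those that a rule selected: for each agonist the 8 largest rises and 8 largest falls among genes with a symbol, an adjusted p under 0.05, no overlap between the groups and signal well above background on every array of at least 1 group; every called LXR target and nr1h3; and up to 4 members of each other list with the smallest p. Between the agonists the 5 largest differences each way and the called LXR targets were selected. In the agonist contrast the values of other LXR targets and of fads2, sc5d, apoa4b.2, per1a, per3 and crygs3 are given outside this rule, after they were seen. Where a group was not well above background on any array, an approximate bound is given in place of a fold. It sets the mean of the brighter group against a floor on each array of the dimmer group. That floor is the array's lowest signal flagged as well above background, or the gene's own signal if higher. It is not the gene's own background threshold. The bound holds no sampling error, so the words at least refer to the observed means.

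Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median of bright probes, no filter, a filter on all arrays, every probe, the mean over the probes of a gene, the excluded array put back, a replicate block, only the 2 groups compared, eBayes with trend and robust, array weights, a 2-fold minimum, an adjusted p under 0.01, and leaving out each array in turn. The scanner files hold no mean signal, so normexp used the median signal of the spot and of its local background. Its offset of 50 is added before the log2 transformation and by construction makes the changes of dim genes smaller. A slide block was planned but each of the 3 slides holds 1 group. Arrays with the same replicate number deviated together from their group means in all 3 pairs of T0901317 and GW3965 (r 0.132 to 0.498), so for that comparison the replicate block is given where it changed a call. For DMSO and T0901317 2 of 3 pairs lay above 0.1, and for DMSO and GW3965 3 of 4, and these comparisons were not taken as paired. The correlations do not clearly separate the comparisons. Agonist arrays of different numbers reached 0.178 (T0901317 replicate 3 and GW3965 replicate 1), above the 0.132 of replicate number 1. Arrays of replicate number 4 deviated together in all 3 comparisons (0.382 to 0.498). The labels do not say what the numbers share, and this reading by comparison was made after the blocked fit had been seen.

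The fit was tested on simulated data in which 200 of 23560 genes were shifted. Changes of 0.5 on the log2 scale were recovered for 25.4%, 26.9% and 32.8% of the shifted genes in the 3 contrasts, changes of 1 for 82.1%, 89.6% and 86.6%, and changes of 2 for 98.5%, 98.5% and 97.0%, with 3.52% to 4.64% of the calls false. The simulated noise was independent between genes and arrays and held no difference between slides. These shares therefore do not give the share of false calls in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.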

Results

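Gene expression was measured in whole zebrafish larvae of the wild-type WIK strain after exposure to agonists of the liver X receptor (LXR), a nuclear receptor that is activated by oxysterols and controls cholesterol and fatty acid genes. Pools of 30 larvae were kept from day 4 to day 6 after fertilization in 0.1% DMSO, in T0901317 or in GW3965, and the treatments were renewed after 24 h. The labels give the doses as 2 mM T0901317 and 1 mM GW3965; a lost micro sign cannot be ruled out, so the doses are printed only as labelled. Each group held 4 arrays, which the design text calls biological quadruplicates. By the same text the authors left out T0901317 replicate 2, which leaves 4 DMSO, 3 T0901317 and 4 GW3965 arrays. On these 11 arrays the 75th percentile of the processed signal lay between 332 and 390 intensity units, and 78.8% to 83.2% of the probes were well above background. Correlations between arrays of 1 group, taken across genes, ran from 0.987 to 0.991. All arrays of a group shared 1 slide and 1 scan, so slide and treatment cannot be told apart in any comparison. Values below are log2 fold changes with the standard error (SE) of the limma fit unless another error is named, and the number of arrays limits their precision.

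The first comparison asks which genes respond to T0901317. Genes of fatty acid and cholesterol metabolism were among the largest rises. The fatty acid desaturase gene fads2 was 17.7-fold higher than in DMSO larvae (log2 fold change 4.14 ± 0.11, n = 3 against 4). The phospholipid transfer protein gene pltp rose 9.55-fold (3.25 ± 0.19) and the stearoyl-CoA desaturase gene scd rose by 2.63 ± 0.22. Transcripts of the fatty acid elongase elovl2 (2.03 ± 0.13), of the fatty acid binding protein fabp4b (2.88 ± 0.23) and of hmgcra (2.04 ± 0.15), which encodes the rate-limiting enzyme of cholesterol synthesis, were also higher. Outside lipid metabolism, the lens crystallin gene crygs2 rose by 3.21 ± 0.18 and jac9 by 2.57 ± 0.34. In DMSO, scd and crygs2 were well above background on 3 of 4 arrays, which leaves their size less certain. Among the largest falls were cbln8 (-2.91 ± 0.32), the C-reactive protein gene crp6 (-2.21 ± 0.35), mfap4.4 (-1.59 ± 0.35) and the apolipoprotein E gene apoea (-1.54 ± 0.08). The call of mfap4.4 ended on leaving out any 1 of 9 arrays, all but DMSO replicate 3 and T0901317 replicate 3 (adjusted p 0.0531 to 0.137). It also ended with no filter, with the excluded array put back, with the replicate number as a block, when only the 2 groups were fitted and without replicate number 4 in all groups (adjusted p 0.0604 to 0.212). The plasma protein gene ahsg2 fell by 1.44 ± 0.17 and slc6a19a.1, which encodes a transporter of neutral amino acids, was 2.45-fold lower. The chitinase gene chia.3 fell by 1.45 ± 0.24, a call that ended without T0901317 replicate 1 (adjusted p = 0.0576). With normexp background correction 6 of these changes kept their call but were over 1.5 times smaller: 0.87 for scd, 1.19 for crygs2, 1.12 for jac9, -1.13 for cbln8, -0.76 for mfap4.4 and -0.47 for slc6a19a.1.

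Of the 17 measured known LXR targets, 7 rose under T0901317, 1 fell and 9 did not pass (9 higher and 1 lower adjusted over the list alone). The list as a whole moved up (camera, adjusted p = 9.54e-07), and the call held with an estimated correlation (adjusted p = 0.0185). Besides pltp and scd, the cholesterol exporter abcg1 rose by 1.19 ± 0.12 (0.75 with normexp), mylipa, which encodes a ubiquitin ligase for the LDL receptor, by 1.52 ± 0.14, and the lipogenic transcription factor srebf1 by 1.27 ± 0.13. The bile acid synthesis gene cyp7a1 rose by 1.33 ± 0.23, a call that ended without T0901317 replicate 1 or replicate 3 (adjusted p 0.0541 to 0.0742) and when only the 2 groups were fitted (adjusted p = 0.0655). The LXR gene itself, nr1h3, was 0.49 ± 0.09 higher, and that call ended without DMSO replicate 2, DMSO replicate 3 or any 1 of the T0901317 arrays (adjusted p 0.0518 to 0.0936). The call of nr1h3 also ended with the replicate number as a block (adjusted p = 0.0567), when only the 2 groups were fitted (adjusted p = 0.0624) and without replicate number 4 in all groups (adjusted p = 0.0883). The member that fell was apoea, 1 of the zebrafish apolipoprotein E genes.

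Cholesterol synthesis and uptake was the list with the most genes called: 17 of 24 members rose, 0 fell and 7 did not pass (21 higher and 0 lower adjusted over the list alone). Its median was 0.84 (camera, adjusted p = 3.69e-26; adjusted p = 0.0185 with an estimated correlation). Examples besides hmgcra were sc5d (1.46 ± 0.11), mvda (1.28 ± 0.11) and the sterol carrier stard4 (0.98 ± 0.08). In fatty acid and triglyceride synthesis, 4 of 24 members rose (fads2, elovl2, scd and srebf1), 1 fell and 19 did not pass (6 higher and 1 lower adjusted over the list alone). That list moved up (camera, adjusted p = 0.00491), but adjusted p = 0.0668 with an estimated correlation and 0.0811 with the excluded array put back. Apolipoproteins and lipoprotein metabolism split: 3 of 22 members rose and 5 fell (6 and 7 adjusted over the list alone), with a negative median (-0.07), a positive mean (0.06) and a camera direction of down (adjusted p = 0.213). There, apoa4a rose by 0.89 ± 0.09 while apoa4b.2 fell by 0.54 ± 0.07.

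Lower shifts were seen for fatty acid oxidation, enterocyte markers and phototransduction. In fatty acid oxidation 0 of 26 members rose and 2 fell (0 and 4 adjusted over the list alone), and 4 of the members had positive values (median -0.19; camera, adjusted p = 9.54e-07; adjusted p = 0.292 with an estimated correlation). Among 26 enterocyte markers 3 fell (slc6a19a.1, apoa4b.1 and chia.3), 0 rose and 23 did not pass (11 lower adjusted over the list alone). Their median was -0.23 (camera, adjusted p = 1.15e-08; adjusted p = 0.292 with an estimated correlation), and it moved beside the falls in apoa4b.1, which is on both lists, and apoa4b.2. The phototransduction and visual cycle list held 52 measured genes, of which 3 fell and 0 rose (13 lower and 2 higher adjusted over the list alone; median -0.24; camera, adjusted p = 4.52e-08; adjusted p = 0.947 with an estimated correlation). This list was written with knowledge of the published theme of the study and is not independent evidence of its direction. In the processed signal the guanylate cyclase activator gene guca1b was at least 1.80-fold lower, since under T0901317 it was not well above background on any array. Its call ended without DMSO replicate 2, DMSO replicate 3, T0901317 replicate 1 or T0901317 replicate 3 (adjusted p 0.0503 to 0.0829). It also ended with normexp (-0.18, adjusted p = 0.218), with the excluded array put back (-0.99, adjusted p = 0.541), with the replicate number as a block (adjusted p = 0.0559) and when only the 2 groups were fitted (adjusted p = 0.0577).

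Other markers gave smaller shifts under T0901317. The hepatocyte list was lower (median -0.14; camera, adjusted p = 0.00763; adjusted p = 0.961 with an estimated correlation) although 1 of 23 members rose and 0 fell (1 and 1 adjusted over the list alone), and its call ended without DMSO replicate 1 or T0901317 replicate 1 (adjusted p 0.0574 to 0.0913). The lens list was not called (median 0.07; camera, adjusted p = 0.0857), and 2 of its 43 members rose (crygs2, and crygs3 by 1.09 ± 0.14; 3 higher and 0 lower adjusted over the list alone). Of 55 genes of PXR and xenobiotic metabolism 2 rose, cyp2x10.2 (1.71 ± 0.18) and the sulfotransferase sult2st1 (0.82 ± 0.10), and 1 fell (2 and 2 adjusted over the list alone). As a whole that list leaned lower without a call (21 of 55 members positive, median -0.07, camera direction of down, adjusted p = 0.0556). The neutrophil gene lyz fell by 0.87 ± 0.14, the macrophage list member slc7a7 by 0.62 ± 0.09 and the slow muscle myosin smyhc1 by 0.52 ± 0.08. Their lists were not called and held 1 lower and 0 higher member each. The neutrophil list had 8 of 16 members positive (1 higher and 1 lower adjusted over the list alone, camera, adjusted p = 0.524). The macrophage list had 14 of 22 positive (2 and 1, adjusted p = 0.958) and the skeletal muscle list 21 of 34 (0 and 1, adjusted p = 0.595). In the circadian clock list 2 of 30 members rose (2 adjusted over the list alone): aanat2, which encodes the enzyme that makes the precursor of melatonin in the pineal gland, by 1.81 ± 0.10, and per3 by 0.48 ± 0.11. The other probe of per3 did not share its sign, and the call of per3 ended on leaving out any 1 of 9 arrays (all but T0901317 replicate 3 and GW3965 replicate 2; adjusted p 0.0534 to 0.161), with no filter (0.0624), with the replicate number as a block (0.0611) and when only the 2 groups were fitted (0.112). Without replicate number 4 in all groups the calls of per3, lyz, smyhc1, crygs3, apoa4b.1 and apoa4b.2 under T0901317 ended (adjusted p 0.0544 to 0.170), and that of apoa4b.1 when only the 2 groups were fitted (adjusted p = 0.0525). The cytochrome oxidase subunit cox6a2 rose by 1.06 ± 0.11.

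Over all 23646 genes tested, 12098 of them with a symbol, 609 passed at an adjusted p under 0.05 for T0901317, 373 higher and 236 lower. Those with a symbol were 155 higher and 117 lower, and 104 of the higher and 29 of the lower genes changed at least 2-fold. The count fell to 258 without DMSO replicate 2, 349 without DMSO replicate 3, 264 without T0901317 replicate 1, 392 without T0901317 replicate 3 and 297 without T0901317 replicate 4. After quantile normalization 309 were higher and 283 lower. A separate fit of only the genes above the median signal, with its own adjustment, called 180 higher and 157 lower. The count was 396 with the excluded array put back, 271 when only the 2 groups were fitted, 932 on testing every probe and 168 without replicate number 4 in all groups.

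**Figure D1:**
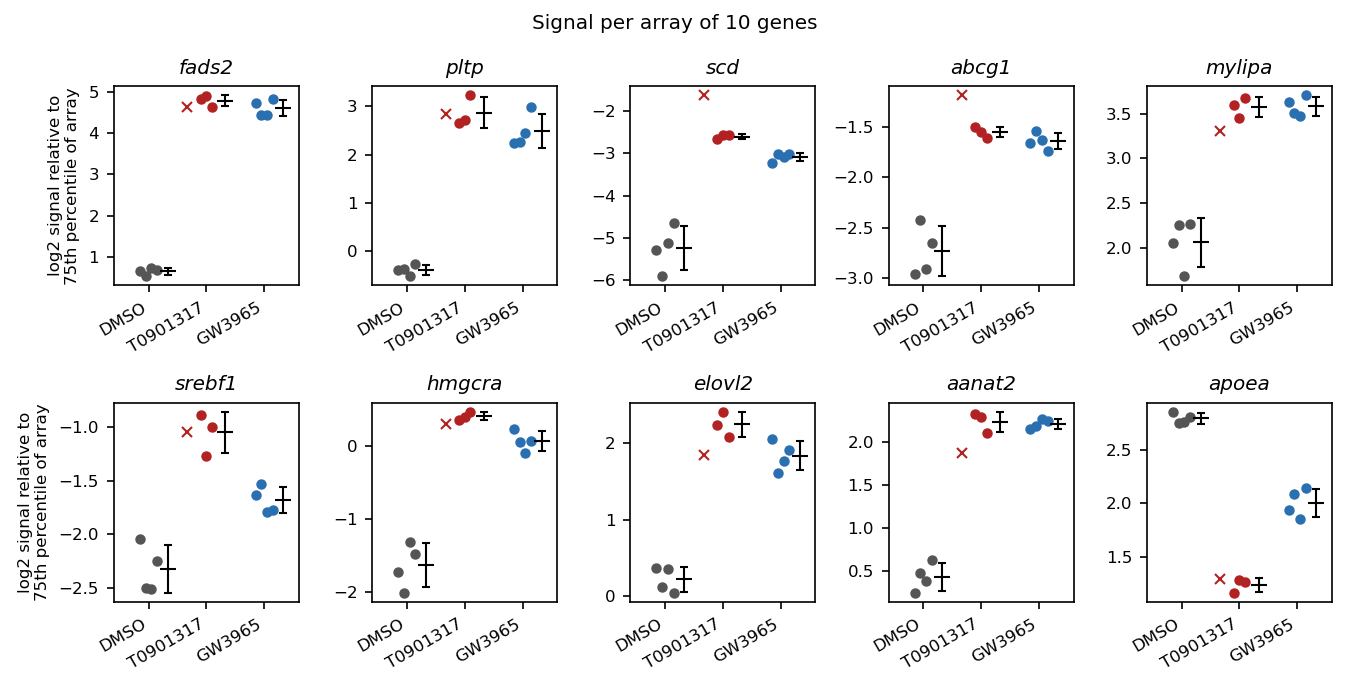
Signal per array of 10 genes on the log2 scale relative to the 75th percentile of each array (y axis) for DMSO, T0901317 and GW3965 (x axis). Points are arrays, crosses are the excluded T0901317 array, and black bars are the mean ± SD of the 4 DMSO, 3 T0901317 and 4 GW3965 arrays; apoea lies lower and the other 9 genes higher than in DMSO under both agonists.

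The second comparison asks the same of GW3965. Again fads2 rose most, 15.6-fold (3.96 ± 0.10, n = 4 against 4), followed by pltp (2.88 ± 0.18), crygs2 (2.43 ± 0.16, or 0.76 with normexp) and scd (2.16 ± 0.21, or 0.60 with normexp). The endothelial lipase gene lipg (1.68 ± 0.14), eepd1 (1.70 ± 0.08), hmgcra (1.69 ± 0.14) and aanat2 (1.78 ± 0.09) were higher too. Among the largest falls of genes above background were those in pkp2, a desmosome component (-2.10 ± 0.20, or -1.39 with normexp), in the angiopoietin gene angpt2b (-1.91 ± 0.23, or -1.02 with normexp), in ftr86 (-1.69 ± 0.16) and in ahsg2 (-1.69 ± 0.15). The other probe of pkp2 did not share its sign, and 1 of 3 other probes of ftr86 did. In the processed signal, transcripts of guca1b, tmem144b, fasn2 and smim1 were at least 1.80-fold, 1.58-fold, 2.67-fold and 1.60-fold lower, with GW3965 signals not well above background. With normexp guca1b kept its call at -0.24, while tmem144b (-0.12), fasn2 (-0.26) and smim1 (-0.16) did not pass (adjusted p 0.119 to 0.465). With the excluded array put back the calls of guca1b (adjusted p = 0.161) and fasn2 (adjusted p = 0.289) ended.

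Of the 17 known LXR targets 8 rose under GW3965, 1 fell and 8 did not pass (11 higher and 1 lower adjusted over the list alone). The list moved up (camera, adjusted p = 1.43e-07; adjusted p = 0.0198 with an estimated correlation). The rise was 2.14-fold for abcg1 (0.69 in log2 units with normexp) and 2.15-fold for cyp7a1, and in log2 units 1.52 ± 0.13 for mylipa, 0.64 ± 0.12 for srebf1 and 0.49 ± 0.09 for nr1h3. The 2 measured apolipoprotein E genes went apart: apoea fell by 0.78 ± 0.08 and apoeb rose by 0.52 ± 0.08. Cholesterol synthesis and uptake had 15 of 24 members higher and 0 lower (18 and 0 adjusted over the list alone; median 0.58; camera, adjusted p = 2.24e-18; adjusted p = 0.0253 with an estimated correlation). Fatty acid and triglyceride synthesis had 7 of 24 members higher and 0 lower (8 and 0 adjusted over the list alone; camera, adjusted p = 0.000120; adjusted p = 0.0198 with an estimated correlation), among them elovl2 (1.62 ± 0.12) and hsd17b12a (0.45 ± 0.08). Over both agonists, the camera calls that held with an estimated correlation were those of the LXR targets and cholesterol lists under each agonist and of fatty acid and triglyceride synthesis under GW3965.

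Fatty acid oxidation was lower under GW3965 (1 of 26 members fell and 0 rose, 1 and 0 adjusted over the list alone; median -0.11; camera, adjusted p = 0.0242; adjusted p = 0.942 with an estimated correlation). The member that fell was pdk4 (-0.87 ± 0.15, or -0.36 with normexp, and adjusted p = 0.0871 with the excluded array put back), which encodes a kinase that inhibits pyruvate dehydrogenase. Without DMSO replicate 1 or GW3965 replicate 4 the list no longer passed (adjusted p 0.0508 to 0.0896), nor did it with array weights (adjusted p = 0.0742). Apolipoproteins and lipoprotein metabolism had 4 of 22 members higher and 2 lower (7 and 5 adjusted over the list alone; camera, adjusted p = 0.426). The phototransduction list, for which the same caution holds, had 2 of 52 members higher and 2 lower (3 and 2 adjusted over the list alone; camera, adjusted p = 0.155), and its member guca1d fell by 0.94 ± 0.18 (-0.47 with normexp, and adjusted p = 0.0643 with the excluded array put back). In the enterocyte list 2 of 26 members fell (2 adjusted over the list alone; camera, adjusted p = 0.153): slc6a19a.1 (-1.25 ± 0.12, or -0.50 with normexp) and ada (-0.64 ± 0.11). The lens list had 1 of 43 members higher and 3 lower (1 and 3 adjusted over the list alone; camera, adjusted p = 0.193), with crygs3 at -1.03 ± 0.13. In that list 31 of 43 members had positive values (median 0.09), although more members were called lower than higher.

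Several single markers moved without a call of their list. Under GW3965 lyz fell by 1.01 ± 0.13, slc7a7 by 0.59 ± 0.08, the myeloid transcription factor spi1b by 0.36 ± 0.06, smyhc1 by 0.57 ± 0.08 and the endothelial gene plvapa by 0.53 ± 0.08, although the other probe of plvapa did not share its sign. The call of spi1b ended with normexp (adjusted p = 0.0514) and with the excluded array put back (adjusted p = 0.156). The macrophage list had 2 of 22 members higher and 3 lower (5 and 4 adjusted over the list alone; camera, adjusted p = 0.858), and the neutrophil list 1 of 16 lower (1 adjusted over the list alone; camera, adjusted p = 0.935). Skeletal muscle had 0 of 34 members higher and 2 lower (0 and 2 adjusted over the list alone, 15 positive, camera, adjusted p = 0.216). Endothelium had 2 of 18 higher and 1 lower (3 and 2 adjusted over the list alone, 13 positive, median 0.10, camera, adjusted p = 0.134). Its higher members were fli1 (0.30 ± 0.07) and plvapb (0.29 ± 0.07), whose calls ended in 15 and 18 of the alternative settings (highest adjusted p 0.186 and 0.170). Of the genes of PXR and xenobiotic metabolism 3 of 55 rose, among them cyp2x10.2 (1.42 ± 0.17) and sult2st1 (0.70 ± 0.09), and 0 fell (3 and 1 adjusted over the list alone). In that list 25 of 55 members had positive values (median -0.05, camera direction of down, adjusted p = 0.935). The thyroid hormone deiodinase dio2 fell by 1.01 ± 0.15, a call that ended with normexp (-0.06, adjusted p = 0.690). It also ended with the excluded array put back (-0.15, adjusted p = 0.917). An added T0901317 array cannot change the fold of GW3965 against DMSO for the same probe, so there another probe stood for dio2. In the circadian clock list 1 of 30 members rose and 3 fell (1 and 3 adjusted over the list alone; camera, adjusted p = 0.338), and per1a was 2.14-fold lower, a call that ended without GW3965 replicate 3 (adjusted p = 0.0555). Without replicate number 4 in all groups the calls of srebf1, nr1h3, guca1d, spi1b and per1a under GW3965 ended (adjusted p 0.0561 to 0.126).

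For GW3965, 1345 genes passed, 289 higher and 1056 lower. Those with a symbol were 176 higher and 396 lower, and 52 of the higher and 232 of the lower genes changed at least 2-fold. The count fell to 837 without DMSO replicate 3, 854 without GW3965 replicate 2, 816 without GW3965 replicate 3 and 863 without GW3965 replicate 4. It was 676 with the excluded T0901317 array put back and 626 without replicate number 4 in all groups. Of the lower calls 66.6% lay in the dimmer part of the genes (below the median signal), against 26.0% of the higher calls. A separate fit of only the genes above the median signal, with its own adjustment, called 329 higher and 455 lower.

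**Figure D2:**
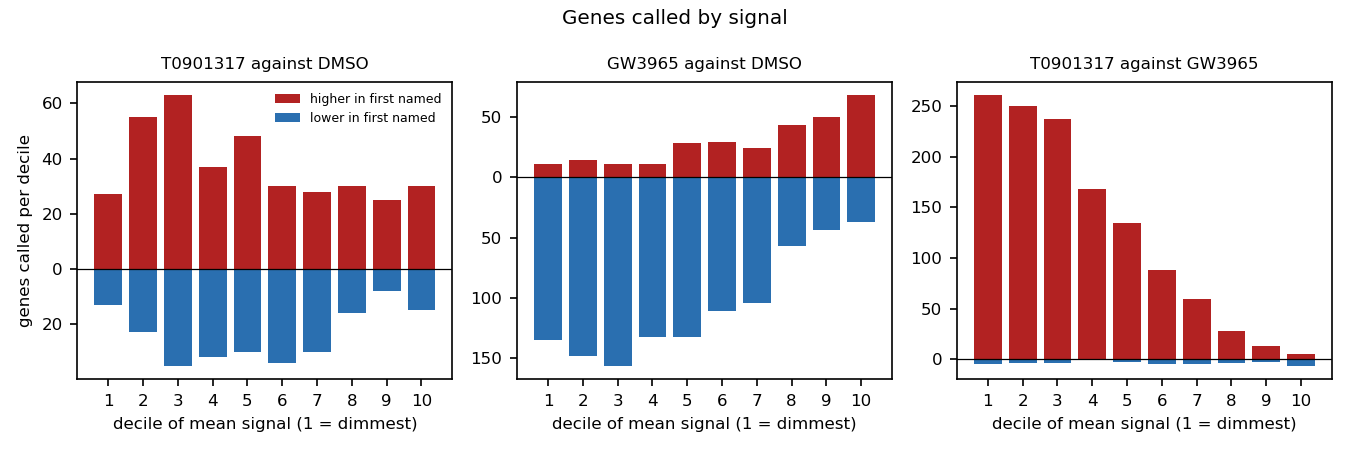
Genes called per decile of mean signal (x axis, 1 is the dimmest) with genes higher in the first named group above 0 and genes lower below 0 (y axis, number of genes). Panels show T0901317 against DMSO, GW3965 against DMSO and T0901317 against GW3965; 66.6% of the 1056 lower calls of GW3965 and 84.4% of the 1245 higher calls of T0901317 against GW3965 lie below the median signal.

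Both agonists shared 306 genes called in the same direction. Of these, 143 were higher (4.56 would be shared by independent lists of these sizes), 84 of them with a symbol, and 163 were lower (10.5), 80 of them with a symbol. Another 85 genes were higher under T0901317 and lower under GW3965, and 0 went the other way. Because both comparisons use the same DMSO arrays, the overlap was recomputed with the 4 DMSO arrays split 2 and 2 over 6 splits, on 23560 genes with a value on every array. Genes higher under both then numbered 75 on average (69 to 88) and genes lower under both 42.8 (33 to 71), against 142 and 162 with shared arrays. Each agonist was then set against 2 DMSO arrays in place of 4, which lowers power. The drop therefore does not measure the sharing of arrays alone. All DMSO arrays also lay on 1 slide, which the splits left shared. In 100 simulated sets without any change the means were 2.49 and 1.11, with ranges of 0 to 200 and 0 to 65. Across genes, which are not independent replicates, the fold changes of the agonists correlated at r = 0.264 (mean 0.0614 with split DMSO arrays, 0.406 in the simulated sets), and their covariance was 0.0229 (0.0162 simulated, 0.00586 with split arrays). The simulated sets ranged from -0.654 to 0.881 for r and from -0.0202 to 0.0710 for the covariance. Both observed values lie within these ranges and do not tell the data from sets without any change. The count of 306 fell to 171 without DMSO replicate 2, 185 without DMSO replicate 3, 171 without T0901317 replicate 1 and 197 without T0901317 replicate 4. It was 176 with the excluded array put back, 161 when only the 2 groups of each comparison were fitted, 528 on testing every probe and 111 without replicate number 4 in all groups.

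The third comparison sets the agonists side by side. The doses differ, so a difference in response cannot be assigned to the compounds. Of the 9 known LXR targets called for either agonist, 8 were called for both in the same direction. For most of them no difference between the agonists passed: T0901317 minus GW3965 was 0.38 for pltp (95% interval -0.04 to 0.80; adjusted p = 0.437), 0.48 for scd (-0.02 to 0.97; adjusted p = 0.399) and 0.09 for abcg1 (-0.18 to 0.36; adjusted p = 0.857). It was -0.01 for mylipa (-0.31 to 0.30; adjusted p = 0.994) and 0.01 for nr1h3 (-0.20 to 0.21; adjusted p = 0.990). Outside that list the difference was 0.18 for fads2 (-0.07 to 0.43; adjusted p = 0.591). These intervals leave room for differences of the sizes given and do not show equal action. Among the LXR targets srebf1 and apoea differed. For srebf1 the difference was 0.63 (0.33 to 0.93; adjusted p = 0.0190), a call that ended without T0901317 replicate 1, T0901317 replicate 4, GW3965 replicate 3 or GW3965 replicate 4 (adjusted p 0.0550 to 0.103), or without replicate number 4 in all groups (adjusted p = 0.195). For apoea it was -0.76 (-0.95 to -0.58; adjusted p = 0.000342), the fall being larger under T0901317.

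Of the 24 cholesterol genes 1 differed past the threshold (1 adjusted over the list alone), sc5d, with 0.48 more under T0901317 (0.23 to 0.72; adjusted p = 0.0308). As a list they were higher under T0901317 (median difference 0.23; camera, adjusted p = 0.000857; adjusted p = 0.894 with an estimated correlation). The apolipoprotein list was lower (4 of 22 members lower and 0 higher, 4 and 0 adjusted over the list alone; camera, adjusted p = 0.01002; adjusted p = 0.894 with an estimated correlation), a call that ended without T0901317 replicate 1 (adjusted p = 0.0587), after quantile normalization (adjusted p = 0.0981) and without replicate number 4 in all groups (adjusted p = 0.0856). Enterocyte markers were lower under T0901317 than under GW3965 (3 of 26 members lower and 0 higher, 3 and 0 adjusted over the list alone; median -0.13; camera, adjusted p = 0.000675; adjusted p = 0.894 with an estimated correlation), beside lower apoa4b.2 (-0.44). The phototransduction list was lower with 0 members past the threshold (camera, adjusted p = 0.000675; adjusted p = 0.894 with an estimated correlation; 0 adjusted over the list alone), and its call ended without T0901317 replicate 3 (adjusted p = 0.247).

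Among the genes with the largest differences were angpt2b (2.83 ± 0.24), jac9 (2.79 ± 0.34) and pkp2 (2.67 ± 0.22), all higher under T0901317; with normexp they were at 1.67, 1.14 and 1.85. In the processed signal the taste receptor gene tas2r203 and the odorant receptor gene or109-6 were at least 3.04-fold and 1.89-fold higher, since their GW3965 signals were not well above background. With normexp tas2r203 kept its call at 0.38 and or109-6 did not pass (0.26, adjusted p = 0.131). Lower under T0901317 were crp6 (-1.85 ± 0.35), cbln8 (-1.80 ± 0.32), chia.3 (-1.05 ± 0.24), cidec (-0.80 ± 0.20) and chia.6 (-0.78 ± 0.15). The call of cbln8 ended with normexp (-0.54, adjusted p = 0.0681) and with the excluded array put back (-1.27, adjusted p = 0.233). The call of chia.3 (-0.70 with normexp) ended without any 1 of the T0901317 arrays or GW3965 replicate 2 (adjusted p 0.05002 to 0.136) and when only the 2 groups were fitted (adjusted p = 0.0502). That of chia.6 ended without T0901317 replicate 1, T0901317 replicate 4 (adjusted p 0.0532 to 0.0638) or replicate number 4 in all groups (adjusted p = 0.0958). The call of cidec ended on leaving out any 1 of 9 arrays, all but DMSO replicate 3 and DMSO replicate 4 (adjusted p 0.0527 to 0.224), and with the replicate number as a block (adjusted p = 0.0689). It also ended after quantile normalization, after cyclic loess, with no filter and without replicate number 4 in all groups (adjusted p 0.0566 to 0.0774). With the block the lists of fatty acid oxidation (camera, adjusted p = 0.0342, against 0.0848 without it) and of PXR and xenobiotic metabolism (0.00410, against 0.139) were lower under T0901317 than under GW3965. Without the block both had an adjusted p = 0.894 with an estimated correlation, and 0 of 26 and 0 of 55 members were called lower. Called higher were 0 of 26 and 1 of 55. The clock gene per1a was 1.74 higher (adjusted p = 0.00144) and per3 0.97 higher (adjusted p = 0.000342) under T0901317 than under GW3965. Of all genes tested, 1277 differed, 1245 higher and 32 lower under T0901317, of which 359 and 19 had a symbol. The count was 823 without T0901317 replicate 1, 797 with normexp and 693 without replicate number 4 in all groups. It was 195 in a separate fit of only the genes above the median signal.

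**Figure D3:**
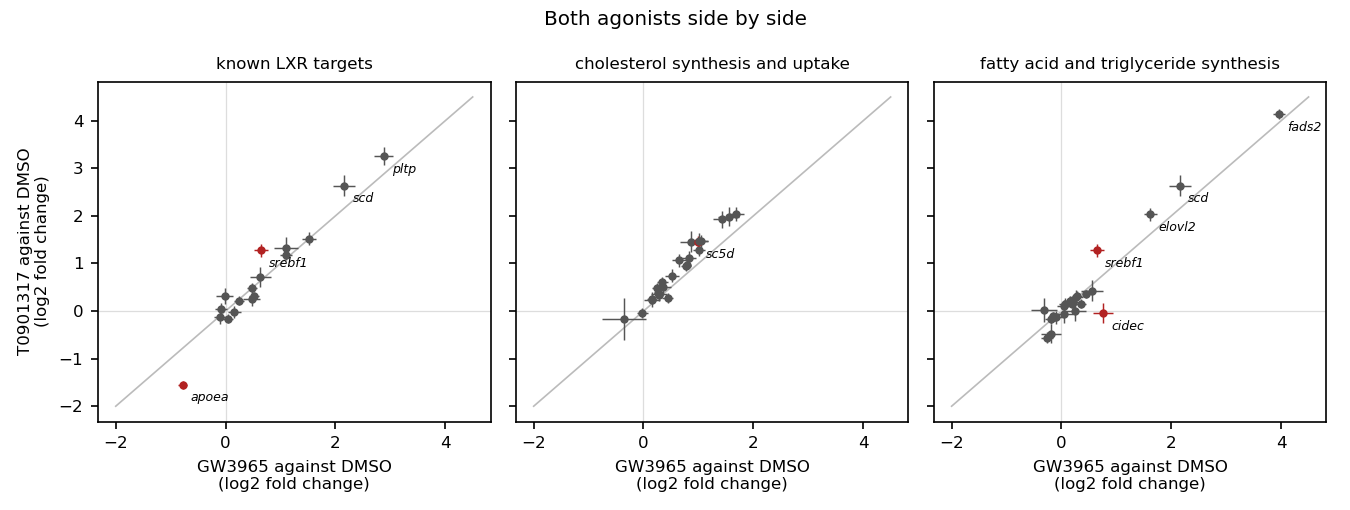
Log2 fold change of T0901317 against DMSO (y axis) plotted on that of GW3965 against DMSO (x axis) for 3 gene lists, with bars for the SE and a grey line of equal change. Red points differ between the agonists at an adjusted p under 0.05; srebf1 (0.63 higher under T0901317) and apoea (-0.76) stand off the line among the LXR targets.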

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

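The tests of second probes, of cyclic loess, of slides, of the clock genes, of the spread of enterocyte genes and of splits that part the pairs were chosen after the result was seen; the splits into all 35 groupings and the quantile test were written down before. The written bound of the quantile test held no condition on leaving out arrays. For the clock and enterocyte tests the bounds were also reworded after their values were seen. Under the first wording both values counted against the explanation, and under the present wording both leave it open.

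In 3 of 15 array measures 1 T0901317 array stood apart from the other arrays of its group, measured as its gap to the nearest array over the range of the group. It was each time the array that the authors left out. The share was 0.981 for the median processed signal (106 units), 0.920 for the percentage of probes well above background (89.8%) and 0.901 for the net signal of the negative controls (48.2 units). The same rule marked 1 of 70 pairs of a gene and a group, fabp4b in the DMSO arrays (0.905), where replicate 3 lay at -1.20 and the others from -1.69 to -1.65. Chance marks about 1 in 20 such groups, and the array measures depend on each other.

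The array left out also carried signal that the comparisons do not use. Of the 24 genes on the LXR target and cholesterol lists that rose under T0901317, 22 lay above every DMSO array in it. The share of all genes that did so was not counted, so these 22 cannot be set against genes in general. The median difference of the 24 genes from DMSO was 1.12 in that array and 1.28 in the other T0901317 arrays.

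The arrays of each comparison were also split in every other way into groups of the same sizes. For T0901317 against DMSO 1 of 35 splits, the real split, gave as many genes (609; highest other 1). For GW3965 against DMSO it was again 1 of 35 (1345, highest other 1). For T0901317 against GW3965 it was 1 of 35 (1277; highest other 10). Arrays of the same number can correlate, however. In each comparison only 8 splits part as many same-number pairs as the real split, too few for a share under 0.05. Among these the highest other counts were 0 for T0901317, 1 for GW3965 and 3 between the agonists. Every other split also mixes both treatments within a group, which widens the spread and favours low counts. The splits therefore do not exclude a random assignment of arrays as the source of the counts, nor a difference between slides.

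Under GW3965 more genes were lower than higher, and in T0901317 against GW3965 more were higher. Quantile normalization left 74.8% of the GW3965 calls lower (78.5% without it) and 91.1% of the calls between the agonists higher (94.6% after cyclic loess). The 74.8% met the bound set before, 70% or more, which counts against a signal-dependent difference between slides as the cause. That bound did not name leaving out arrays. On leaving out 1 array the share ran from 69.1% to 78.5%, which reaches below 70%, so the question is left open here. The median change over all genes also depended on signal. It went from -0.15 in the dimmest decile to 0.09 in the brightest under GW3965, and from 0.24 to -0.04 between the agonists. A second probe of the same gene followed 60 of 190 lower calls (31.6%) and 72 of 110 higher calls (65.5%) of GW3965 (Fisher's exact p = 1.93e-08), and between the agonists 30 of 152 higher (19.7%) and 10 of 12 lower calls (83.3%; p = 1.29e-05), so calls resting on single probes could account for part of the excess. The gap stayed with second probes well above background on every array. These followed 52 of 157 lower (33.1%) and 70 of 105 higher calls (66.7%) of GW3965. Between the agonists they followed 18 of 106 higher (17.0%) and 10 of 12 lower calls (83.3%). In these genes second probes near background do not account for the gap. The number of slides that hold more than 1 group is 0, so slide and agonist cannot be told apart. The doses also differ between the agonists, and their part was not tested.

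Transcripts of aanat2, which follow the time of day, were higher under both agonists. If larvae had been collected at another hour, the other 29 clock genes could also move. Their root mean square change lay at percentile 62.7 of 10000 random lists under T0901317 and at 77.4 under GW3965, which does not decide the matter. With 0 slides holding more than 1 group, the slide of the DMSO arrays and the agonists cannot be told apart either.

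Enterocyte genes were lower under T0901317, with 21 of 26 negative. Fewer enterocytes or less gut RNA could lower them all alike. In 7 of 26 (26.9%, exact interval 11.6% to 47.8%) the change lay over 3 standard errors from the median of the list, too wide an interval to decide. The slide also stays open here (0 slides hold more than 1 group).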

How the results depend on the processing

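Leaving out replicate number 4, cyclic loess and the brighter genes alone were chosen after the data were seen; the other alternatives were planned. The order of counts below is T0901317 (609 in the report), GW3965 (1345), T0901317 against GW3965 (1277) and both agonists in the same direction (306). No called list and no called gene selected by the rule changed its direction in the settings where directions were compared. Directions were not compared on testing every probe or in the brighter genes alone. For genes they were also not compared with the mean over the probes of a gene.

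Normexp gave 797 genes between the agonists, and with it 12 of 131 called named genes no longer passed, among them guca1b under T0901317, tmem144b, fasn2, smim1, dio2 and spi1b under GW3965, and cbln8 and or109-6 between the agonists; the cause was not tested. With T0901317 replicate 2 put back the counts were 396, 676 and 176 for T0901317, GW3965 and both, and 28 of 131 named genes were lost. These include guca1b and mfap4.4 under T0901317, guca1b, guca1d, pdk4, fasn2, spi1b and dio2 under GW3965, and cbln8 between the agonists, besides fatty acid and triglyceride synthesis under T0901317 (adjusted p = 0.0811). The brightest probe of each gene was chosen anew in this setting, and another probe then stood for dio2. The cause of the other losses was not tested. Fitting only the 2 groups compared gave 271 for T0901317 and 161 for both, with fewer arrays to estimate the spread. Testing every probe gave 932 and 528, where a gene can count more than once. A 2-fold minimum left 133, 284, 646 and 59, and an adjusted p under 0.01 left 161, 503, 743 and 116, both stricter by construction.

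Leaving out 1 array gave 258 to 615 for T0901317, 816 to 1332 for GW3965, 823 to 1275 between the agonists and 171 to 297 for both. Without replicate number 4 in all groups the counts were 168, 626, 693 and 111, and 50 of 131 called named genes were lost; fewer arrays lower the power. The brighter genes alone gave 337, 784 and 195 in the 3 comparisons, with fewer genes tested.

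The share of GW3965 calls that were higher, 21.5% in the report, was 31.3% with normexp (316 higher and 693 lower), 30.0% after median scaling (388 and 905), 25.2% after quantile normalization and 22.2% after cyclic loess. In the separate fit of only the brighter genes it was 42.0%. For T0901317 it was 61.2% and 52.2% after quantile normalization (309 and 283). Of 23 called lists 5 held with an estimated correlation and 18 each after quantile normalization and cyclic loess. Both ended oxidative stress and oxidative phosphorylation under GW3965 and oxidative stress and the unfolded protein response between the agonists. Quantile normalization also ended the apolipoproteins between the agonists, and cyclic loess the epidermis under T0901317.

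The replicate block gave 591, 1600, 1258 and 314 genes, of which 422, 1202 and 1097 were shared with the 3 comparisons of the report. Of 131 called named genes it ended 17, among them nr1h3, guca1b and per3 under T0901317, and it added 16. Same-number arrays correlated above 0.1 in 8 of 10 pairs (0.0256 to 0.498), and 5 of 11 arrays correlated best with their own number. Only the agonists had every pair above 0.1. There, among the genes selected by the rule and the lists, the block changed no call besides cidec, fatty acid oxidation and PXR. Genes given outside the rule in that comparison were not followed through the alternatives.

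The series table was not run because its values are identical to the scanner files. A slide block could not be fitted because each slide holds 1 group. Normexp used the median signal for want of a mean signal. Genes with a group not well above background carry bounds on the processed signal only, and with normexp 11 of 48, 18 of 71 and 6 of 12 called named genes changed over 1.5 times less in the 3 comparisons.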

Other observations

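The tests here were planned, except cyclic loess and leaving out replicate number 4, which were chosen after the data were seen. The comparison of crygs3 between the agonists was picked out after its value was seen. Several lists that the report does not describe shifted by small amounts. Under GW3965 genes of oxidative stress defence (Nrf2) had a median of 0.14 (camera, adjusted p = 0.00442; adjusted p = 0.763 with an estimated correlation), with 1 of 24 members higher. Oxidative phosphorylation had a median of 0.08 (camera, adjusted p = 0.00442; adjusted p = 0.977 with an estimated correlation), a call that ended without DMSO replicate 2 (adjusted p = 0.116), and its member cox6a2 rose by 0.73 ± 0.10. Both calls ended after quantile normalization (adjusted p = 0.139 and 0.807). AhR targets had a median of 0.14 with 0 of 12 members called (camera, adjusted p = 0.0258; adjusted p = 0.664 with an estimated correlation). That call ended without DMSO replicate 4, T0901317 replicate 1, T0901317 replicate 4 or GW3965 replicate 1 (adjusted p 0.0544 to 0.0665), with the mean over all probes (adjusted p = 0.190) and without replicate number 4 in all groups (adjusted p = 0.104). Under T0901317 epidermis markers had a median of 0.13 with 0 of 29 called (camera, adjusted p = 0.0407; adjusted p = 0.961 with an estimated correlation), which ended on leaving out any 1 of 8 arrays, all but DMSO replicate 1, DMSO replicate 3 and T0901317 replicate 4 (adjusted p 0.0527 to 0.663). It also ended in 7 other settings: normexp, no filter, the excluded array put back, the replicate block, only the 2 groups, the mean over all probes and cyclic loess (adjusted p 0.0619 to 0.591).

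Between the agonists, cartilage and bone (median 0.14; camera, adjusted p = 0.0238) and proliferation (0.17; adjusted p = 0.0238) were higher under T0901317. Oxidative stress defence (-0.07; adjusted p = 0.0339) and the unfolded protein response (-0.06; adjusted p = 0.0238) were lower. All 4 had an adjusted p = 0.894 with an estimated correlation. Each ended when 1 of 3 or 4 arrays was left out: T0901317 replicate 3, GW3965 replicate 2 or GW3965 replicate 4 for cartilage and bone (0.0599 to 0.361), and T0901317 replicate 1, T0901317 replicate 3 or GW3965 replicate 4 for proliferation (0.131 to 0.404). For oxidative stress they were T0901317 replicate 1, T0901317 replicate 4, GW3965 replicate 1 or GW3965 replicate 3 (0.0751 to 0.277), and for the unfolded protein response T0901317 replicate 1, GW3965 replicate 1 or GW3965 replicate 3 (0.0552 to 0.201). The first 2 also ended with the excluded array put back (0.381), and the last 2 after quantile normalization (0.549 and 0.380). With the mean over all probes all but cartilage and bone ended (0.0708 to 0.268). The lens crystallin gene crygs3 was 2.12 higher under T0901317 than under GW3965 (95% interval 1.81 to 2.44; adjusted p = 7.25e-05).

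Groups did not overlap on any array for 2967 genes under T0901317 (12.5%, 5.71% by chance), 3424 under GW3965 (14.5%, 2.86% by chance) and 3544 between the agonists (15.0%, 5.71% by chance).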
